A study of Mus musculus with 22 samples.

How the data were processed

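The series comprised 22 samples of mouse prefrontal cortex. Per the labels, 12 were 5hmC capture libraries in 6 groups of 2, 4 were HIF1A chromatin immunoprecipitation libraries in 2 groups of 2, and 6 were RNA libraries in 2 groups of 3; groups and replicate numbers were taken from the sample titles. The labels do not state whether samples of a group came from separate animals. They name 2 further region lists, which were not used here.

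Per the submitters' processing notes, the tools included Bowtie 1.1.0, bedtools, TopHat2 2.0.13 and Cuffdiff 2.2.1, and the genome build was mm9. The RNA table has the column layout of a Cuffdiff comparison, and per its file header it gives the authors' FPKM value for the control group and for the stressed group, a fragment count scaled to transcript length and library size, with the libraries of each group combined. The authors' log2 fold change, per the file headers, is stressed over control; recomputed from the FPKM values it differed by at most 5.02e-05 where both were above 0. The same table holds a yes or no call by the authors; the threshold behind it is not given in the sources used here, and the table holds no p-value. Its 34411 lines list 23488 genes, once per RefSeq accession, with 1 pair of values per gene. Of these, 22655 symbols matched a table of mouse gene names and 23250 accessions a RefSeq table of assembly GRCm38, used for names alone. Exact zeros can be failed estimates: 5267 genes were listed at 0 in both groups, 498 in the stressed group alone and 617 in control alone. Rn45s had a log2 of 0 in the authors' deposited table in spite of values of 0 and 289.9 FPKM.

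The 5 region lists give chromosome, start, end, a peak name and the authors' score per peak, as deposited. Peak names show that MACS called the peaks; its version, its settings and whether libraries were pooled before calling are not given in the sources used here. Scores began just above 50 in each list. The gained and conserved HIF1A regions used peak numbers 1 to 462 with none in both lists, so they are parts of 1 set of stressed peaks, and lost regions carried numbers up to 239. The gained 5hmC regions came from 2896 peaks, of which 316 gave more than 1 region, and the lost regions from 1244 peaks. Scores were used to rank and filter regions within a list. Coordinates are printed as listed, on build mm9; whether starts count from 0 or 1 is not given in the sources used here, and length was taken as end minus start. No annotation of build mm9 was used, so regions were not assigned to genes, and the planned comparison of expression at genes with 5hmC or HIF1A regions was not run.

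Because the RNA table holds group values, the calls of the authors' deposited table stand as the test of single genes, and no test was added. The design written before the data were examined had foreseen q-values at 0.05 for such a table; the call without q was used in their place. Without p-values no count adjusted over the list alone could be given. Differences between groups were computed as log2(FPKM + 1), a scale that understates changes of low genes, over the 12971 genes with at least 1 FPKM in either group. For each of 32 gene lists fixed before the data were examined, the median difference of lists with at least 5 measured members was placed among 10000 random lists drawn to match the members over 20 bins of mean expression. This percentile describes these values and is not a test across animals. Bins held equal numbers of genes, so matching is coarse among the most abundant genes, where the difference between groups changed with level. Percentiles of lists of abundant genes carry that limit. Genes were named by a rule fixed beforehand: the 12 largest rises and the 12 largest falls among called genes with at least 1 FPKM in the higher group, called members of the lists up to 4 each, and Tet1, Tet2, Tet3 and Hif1a. Where no rise was called the rule asked for the 6 smallest p-values; as none exist, the 6 largest differences in log2(FPKM + 1) were taken. Uncalled members of lists and other genes given as examples were chosen after their values were seen. The 3 highest-scoring regions of each list and each HIF1A region overlapping a 5hmC region were also named.

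Gained and lost regions were counted and compared by two-sided exact binomial tests with Clopper-Pearson 95% intervals, and lengths by permutation tests with 100000 resamples. Shares per chromosome were compared by Fisher exact tests. Proximity of HIF1A and 5hmC regions was counted at an overlap of at least 1 bp, within 1 kb and within 10 kb, and set against 10000 placements of the HIF1A regions at random positions between the first and last listed region of their chromosome, a two-sided permutation of positions whose p-value comes from the placements at least as extreme. Alternatives covered the pseudocount (0.1 and 0.01), the filter on low values, quantile normalization, median centring, score limits, merging of regions within 1 kb, and overlap definitions. The steps were tested on simulated data: on the 12971 genes, a list shifted 2-fold was placed outside the central 95% of random lists in 20 of 20 runs, a list shifted 1.5-fold in 17 of 20, a list shifted 1.25-fold in 9 of 20, and a list left as it was in 4 of 100. Random regions differed from placements at p under 0.05 in 5 of 100 runs, and 15 planted neighbours among 100 regions were detected in 100 of 100. Simulated regions were placed independently on 1 chromosome, and simulated genes varied independently without a trend over expression. These rates therefore need not hold for the crowded regions and level-dependent differences of the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Read depth of the samples was not given with these values, so precision per gene is unknown.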

Results

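The series profiled prefrontal cortex of mice with and without chronic restraint stress, a repeated confinement of the animal used as a psychological stressor. It comprised 22 samples in 10 groups. Captured DNA carrying 5-hydroxymethylcytosine (5hmC), the base that TET enzymes make from methylated cytosine, was sequenced in 12 samples of 6 groups that combined wild-type, Tet1-knockout and Tet2-knockout genotypes with stress. Chromatin immunoprecipitation of HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, was sequenced in 4 wild-type samples of 2 groups. RNA was sequenced in 3 control and 3 stressed samples. The values analysed were 1 expression value per RNA group and 5 lists of regions, so no value below has a replicate error of its own, and sequencing depth per sample is unknown. The knockout groups and the labelled Tet2 wild-type control group enter no comparison below and were not analysed here.

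The RNA comparison asked which transcripts differed in prefrontal cortex after chronic stress. The authors' deposited table called 233 of 23488 genes, of which 233 fell and 0 rose in the stressed group. Among called genes with a value above 0 in both groups, the steepest falls were in Rpph1, the RNA component of ribonuclease P, from 829.8 to 3.49 FPKM, and in Rmrp, the RNA component of the related ribonuclease MRP, from 640.5 to 5.13 FPKM; in the authors' deposited table these were log2 changes of -7.89 and -6.96. Rnu12, the U12 RNA of the minor spliceosome, was called in the authors' deposited table at 88.2 FPKM in control and listed at 0 after stress. Among the largest called falls in the authors' deposited table were also Kiss1, which encodes kisspeptin, from 33.2 to 1.41 FPKM, Nrtn, which encodes the growth factor neurturin, from 21.7 to 0.683, and Gng13, a G protein gamma subunit, from 1069.8 to 45.3.

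The remaining genes of the 12 largest called falls follow. Gm1673 had 917.96 FPKM in control and 23.4 after stress, a log2 change of -5.29 in the authors' deposited table, and Bola2, which acts in the handling of iron-sulfur clusters, had 1726 and 58.7 FPKM, a log2 change of -4.88. Gm11127 and the crystallin gene Crybb3 had log2 changes of -4.95 and -4.89 in the authors' deposited table. The histone H4 gene Hist1h4c, at 3.88 FPKM in control, and 4930451I11Rik, at 2.06 FPKM, were called in the authors' deposited table and listed at 0 after stress; Vmo1, below 1 FPKM in control and named here after its value was seen, was the remaining called gene listed at 0. Among the 229 called genes with a value above 0 in both groups, the authors' deposited table gave a median log2 change of -2.61, and the smallest fall was -1.64. That median corresponds to 6.12-fold lower expression in the authors' deposited table.

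No rise was called, so the 6 largest higher values are given as not passing. Mir6392, Rn45s, Mir6516, Snora41 and Snora69, all small or ribosomal RNA genes, were listed at 0 in control and at 306.2, 289.9, 161.1, 114.7 and 48.1 FPKM in the stressed group, and none was called in the authors' deposited table. Gh, the growth hormone gene, had the authors' values of 0.0184 FPKM in control and 27.2 after stress, and it was not called in the authors' deposited table. For genes with at least 1 FPKM in control, leaving out microRNA, small nucleolar RNA and ribosomal RNA genes and picked after their values were seen, the highest ratio belonged to Atp6v0c, a subunit of the vacuolar proton pump, at 66.8 against 308.1 FPKM, followed by Ndufs5, a complex I subunit, at 26.0 against 73.6 FPKM; neither was called in the authors' deposited table.

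The TET enzymes and HIF1A, around which the assays were built, had no call in the authors' deposited table. The authors' values were 0.938 FPKM in control and 0.997 in stressed cortex for Tet1, 4.33 and 5.43 for Tet2, 6.26 and 5.13 for Tet3, and 13.6 and 16.2 for Hif1a. Of the 18 measured genes of the TET and DNA methylation machinery, 13 had a higher and 5 a lower stressed value, with a median log2 difference of 0.11 and 0 calls in the authors' deposited table. Of 13 HIF pathway components, 9 were higher and 4 lower, with a median of 0.16 but a mean of -0.11. The list median lay at the 97.6 percentile of random lists, above their central 95%, but at the 93.7 percentile and inside it after quantile normalization. Epas1, the second HIF alpha subunit, had 22.5 and 28.8 FPKM, while Vhl, which targets HIF alpha for destruction, had 36.2 and 17.4 FPKM. Egln2, the largest change of this list, had 132.1 and 26.4 FPKM. The 30 measured hypoxia and HIF1 target genes split into 14 higher and 16 lower with a median of -0.05, which turned to 0.32 after quantile normalization. Of these, 3 were at least 2-fold lower and 0 at least 2-fold higher. Vegfa had 15.9 and 20.5 FPKM, while Tpi1 had 744.0 and 327.7. The 23 measured glucocorticoid-responsive genes split into 10 higher and 13 lower, with a median of -0.04 at the 61.3 percentile, inside the random range, and of 0.07 after quantile normalization; 5 were at least 2-fold lower and 0 at least 2-fold higher. Fkbp5, a feedback gene of the glucocorticoid receptor, had 7.83 and 7.58 FPKM, while the metallothionein gene Mt1 had 1352 and 308.4 FPKM and Tsc22d3, a glucocorticoid-induced leucine zipper gene, 77.4 and 37.3 FPKM. The kinase gene Sgk1 had 19.01 and 27.9 FPKM; neither list had a call in the authors' deposited table.

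Of 12971 genes with at least 1 FPKM in either group, 1725 were at least 2-fold lower and 22 at least 2-fold higher on the log2(FPKM + 1) scale, and these became 1078 and 187 after quantile normalization of the 2 value columns. Grouped by the mean of both values, the 6194 genes with 1 to 10 FPKM had a median log2 difference of 0.04, the 792 genes with 100 to 1000 FPKM had -0.85, and the 49 genes above 1000 FPKM had -2.55. Grouped by the stressed value, the medians were 0.02 for 6395 genes with 1 to 10 FPKM and -0.39 for 588 genes with 100 to 1000 FPKM, so the size of this difference depends on the value used for grouping. Many steeply lower values carried no call: of 690 genes with at least 1 FPKM in control and at least a 4-fold lower stressed value, 206 were called in the authors' deposited table. Rplp1, a ribosomal stalk protein gene, had 9733 and 877.3 FPKM without a call in the authors' deposited table. The sum over all genes was 660467 FPKM in control and 334641 in the stressed group. Values per library and p-values were not used here, so whether a difference exceeded the spread between the 3 samples of a group rests on the authors' calls.

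**Figure D1:**
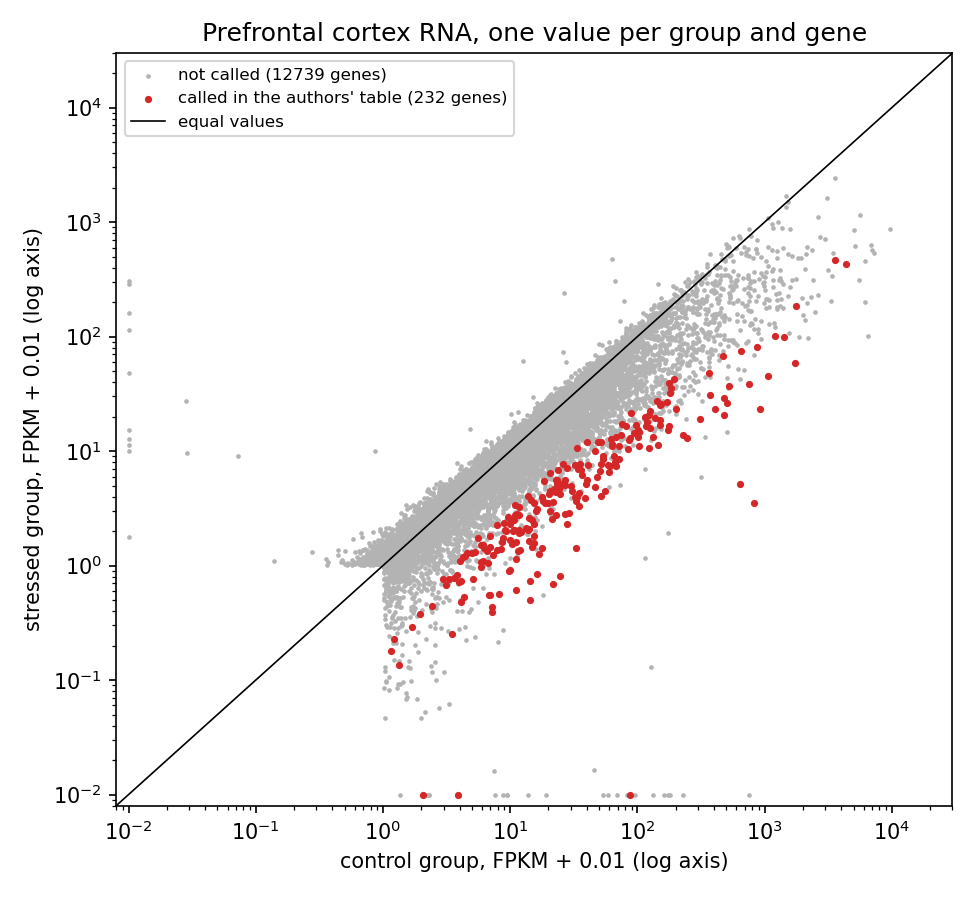
FPKM in the stressed group against FPKM in the control group for the 12971 genes with at least 1 FPKM in either, both on log axes after adding 0.01, each point being 1 gene and the line marking equal values. The 232 called genes of this set lie below the line, and the cloud bends below it at high control values.

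Among the fixed gene lists, the immediate early genes, which neurons switch on with activity, were low against other genes of their level. Of 27 measured members 22 were lower and 5 higher in the stressed group, with a median log2 difference of -0.52, at the 0.04 percentile of 10000 random lists; after quantile normalization these were -0.14 and the 0.56 percentile. The list of nuclear and non-coding RNAs fixed as a sign of RNA quality lay at the 99.7 percentile in the same groups. Egr2, a zinc finger transcription factor, was called in the authors' deposited table and fell from 4.0 to 1.08 FPKM, a log2 change of -1.89. The authors' values for members that were not called were 14.3 and 7.67 FPKM for Fos, 125.2 and 78.1 for Egr1, and 24.0 and 6.67 for Gadd45g. Jun and Btg2 were higher, at 5.93 and 8.16 FPKM and at 2.35 and 4.33 FPKM, without a call in the authors' deposited table.

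Of 41 ribosomal protein genes 40 were lower, with a median of -1.68 at the 0.225 percentile and 0 calls in the authors' deposited table; after quantile normalization 11 were higher, with a median of -0.60 at the 0.515 percentile. Without that normalization the RNA quality list lay at the 99.7 percentile and the blood and hypothalamic marker lists at the 1.39 and 1.51 percentiles. Rps15 had 7274 and 536.4 FPKM. Of 34 subunits of oxidative phosphorylation 30 were lower, with a median of -1.35 at the 8.76 percentile, inside the central 95% of random lists. After quantile normalization the median was -0.24, with 14 higher. With no filter on low values the percentile was 2.23, outside that range, but the median was the same -1.35. Only the random lists differed there, drawn from bins that held more genes, so this shift is not a change in the subunits. The authors' deposited table called Ndufa5, which fell from 1206 to 101.8 FPKM, and Ndufs6, which fell from 866.99 to 81.1 FPKM, both complex I subunits. Of 16 glycolysis enzymes 12 were lower, with a median of -0.30, but this lay at the 92.6 percentile, inside the random range. After quantile normalization the median was 0.81 at the 98.8 percentile, above that range.

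Neuropeptide genes held further calls. Of the 22 measured stress hormone receptors and neuropeptides, 15 were lower and 7 higher, with a median of -0.36 at the 3.64 percentile, inside the central 95% of random lists; the median turned to 0.12 after quantile normalization. Cort, the cortistatin precursor, fell from 67.7 to 7.46 FPKM and Cartpt, the precursor of cocaine- and amphetamine-regulated transcript peptide, from 10.0 to 1.65 FPKM; both were called in the authors' deposited table, with log2 changes of -3.18 and -2.60. Sst, the somatostatin gene, had 823.5 and 367.4 FPKM and Crh, the corticotropin-releasing hormone gene, 5.48 and 3.42 FPKM, without calls in the authors' deposited table. The receptor gene Nr3c1 had 18.3 and 16.9 FPKM. Oxt and Avp, members of this list and of the hypothalamic marker list, had 5.31 and 0.227 FPKM and 3.29 and 0.494 FPKM without calls in the authors' deposited table; that marker list lay below its random range, at the 1.51 percentile.

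Some neuronal lists lay above their matched random lists, as did the list fixed as a sign of RNA quality, at the 99.7 percentile. The 14 pan-neuronal and excitatory markers had 9 members higher and 5 lower, a median of 0.11 and the 99.9 percentile, but a mean of -0.17. Snap25 had 1480.3 and 1695 FPKM, while Nrgn had 5028 and 859.7 and Syn1 449.8 and 231.3. Of 20 genes of GABA synthesis, transport and reception 16 were higher and 4 lower, with a median of 0.13 at the 99.7 percentile. Gad1 had 88.7 and 103.0 FPKM, but Gabrd, the largest change of this list, had 147.2 and 32.2 FPKM. The 6 measured neurotrophins and receptors had a median of 0.21 at the 98.9 percentile, which became 86.2 with no filter on low values and 97.3 after quantile normalization, both inside the central 95%, with Ntrk2 at 77.4 and 88.2 FPKM but Bdnf at 9.91 and 6.93. The 22 glutamate receptors had a median of 0.04 at the 85.1 percentile, inside the range, as were 17 cortical layer markers at the 28.8 and 13 interneuron markers at the 49.2 percentile. None of these 6 lists had a call in the authors' deposited table.

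The 5 measured blood cell markers were lower after stress, with a median of -1.68 at the 1.39 percentile. After quantile normalization this became -0.84 at the 3.54 percentile, inside the range. The alpha-globin gene Hba-a1 had 623.2 and 51.7 FPKM and the beta-globin gene Hbb-bs 45.3 and 0.0063 FPKM. The other beta-globin entries fell less, Hbb-b1 from 263.3 to 81.4 FPKM and Hbb-bt from 32.9 to 16.8 FPKM. None of these was called in the authors' deposited table. Of 9 measured thalamic, hypothalamic and hindbrain markers 7 were lower, with a median of -0.41 at the 1.51 percentile, among them Agrp, a hypothalamic peptide gene, at 2.64 and 0.454 FPKM. Of 8 nuclear and non-coding RNAs, a list fixed as a sign of RNA quality, 5 were higher, with a median of 0.16 at the 99.7 percentile. In all, 9 of 29 lists lay outside the central 95% of their random lists, 4 below and 5 above, where 1.45 would be outside by chance if lists were random draws. Quantile normalization raised the median of the 12971 genes from -0.04 to 0.18 and turned the sign of 12 list medians, so a list's position among its random lists was the comparison used.

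**Figure D2:**
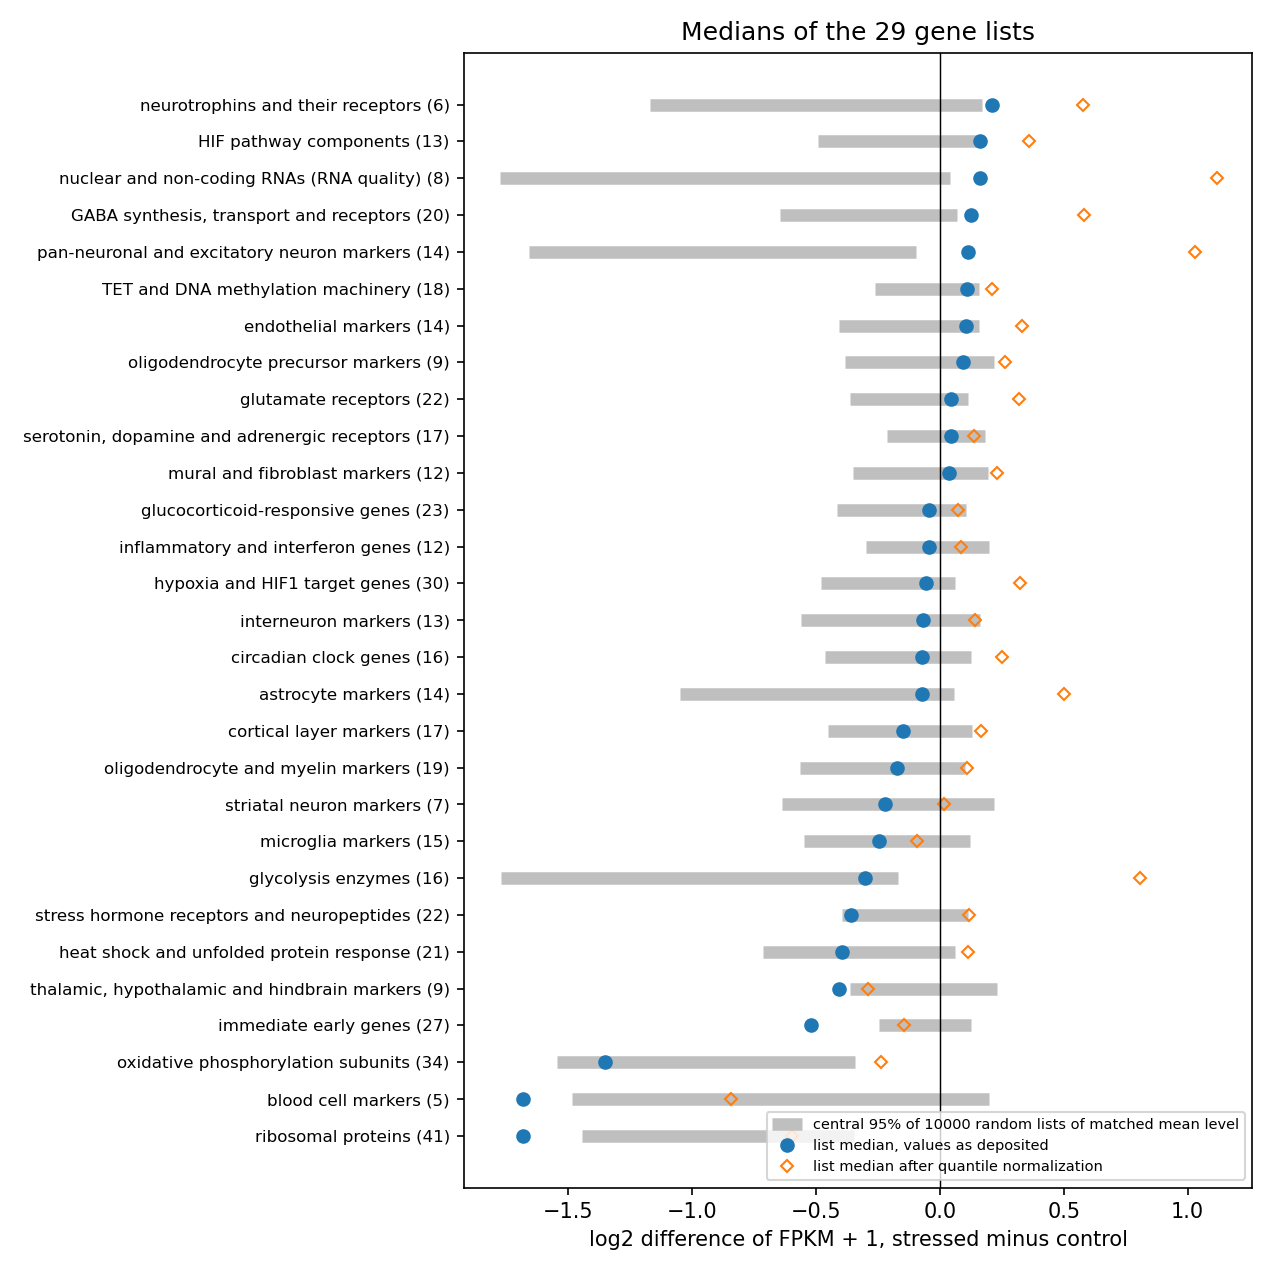
Median log2 difference of FPKM + 1, stressed minus control, for the 29 lists with at least 5 measured members (number in parentheses), as deposited (circles) and after quantile normalization (diamonds). Grey bars give the central 95% of 10000 random lists for the values as deposited, and 9 circles lie outside their bar.

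The 5hmC comparison asked where this mark appeared or disappeared with stress in wild-type cortex. The authors' lists held 3239 gained and 1251 lost regions, so 72.1% of 4490 changed regions were gains (95% exact binomial interval 70.8 to 73.4%, two-sided exact binomial p = 5.1e-200). Gains outnumbered losses on each of the 19 autosomes. Gained regions were short, with a median length of 94 bp against 586 bp for lost regions (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The lost list therefore covered more sequence, 753.5 kb against 329.3 kb. Lower and upper quartiles of length were 88 and 112 bp for gained and 488.5 and 704 bp for lost regions. Of gained peaks 316 gave more than 1 region, and of lost peaks 7. Rows of these lists are thus unlike units, and whether both lists were made alike is not given in the sources used here. The share of gains and the p-values therefore compare list rows, not amounts of 5hmC. Chromosome X held 1 gained region and 0 lost regions, a share of 0.0309% of gains (95% exact interval 0.000782 to 0.172%), and chromosome Y and the mitochondrial genome held 0. Unchanged peaks are not listed, so these shares have no baseline of all 5hmC peaks per chromosome.

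The highest-scoring gained region lay on chromosome 1 from 191555678 to 191555772, with a score of 428.2. Next came a pair on chromosome 18, from 12001530 to 12001624 and from 12001650 to 12001785, which carried the same peak name and the score 333.7. The highest-scoring lost regions lay on chromosome 17 from 34084756 to 34085799 (score 312.6), on chromosome 11 from 120149842 to 120151537 (score 252.2) and on chromosome 5 from 123436513 to 123437510 (score 226.2). Scores are the authors' values per peak, and positions are on build mm9, for which gene annotation was not used here. Gained and lost regions never overlapped, which such lists can show by construction. Within 10 kb of a lost region lay 163 gained ones, against 36.96 on average in random placements with a central 95% range of 25 to 49 (two-sided permutation of positions, p = 0.0002, the smallest that 10000 placements can give). This count took regions of the same peak separately, and placements did not follow genes or sequence composition. Regions are not independent replicates, so the binomial p describes the lists and not the animals; the intervals cover counting error only.

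**Figure D3:**
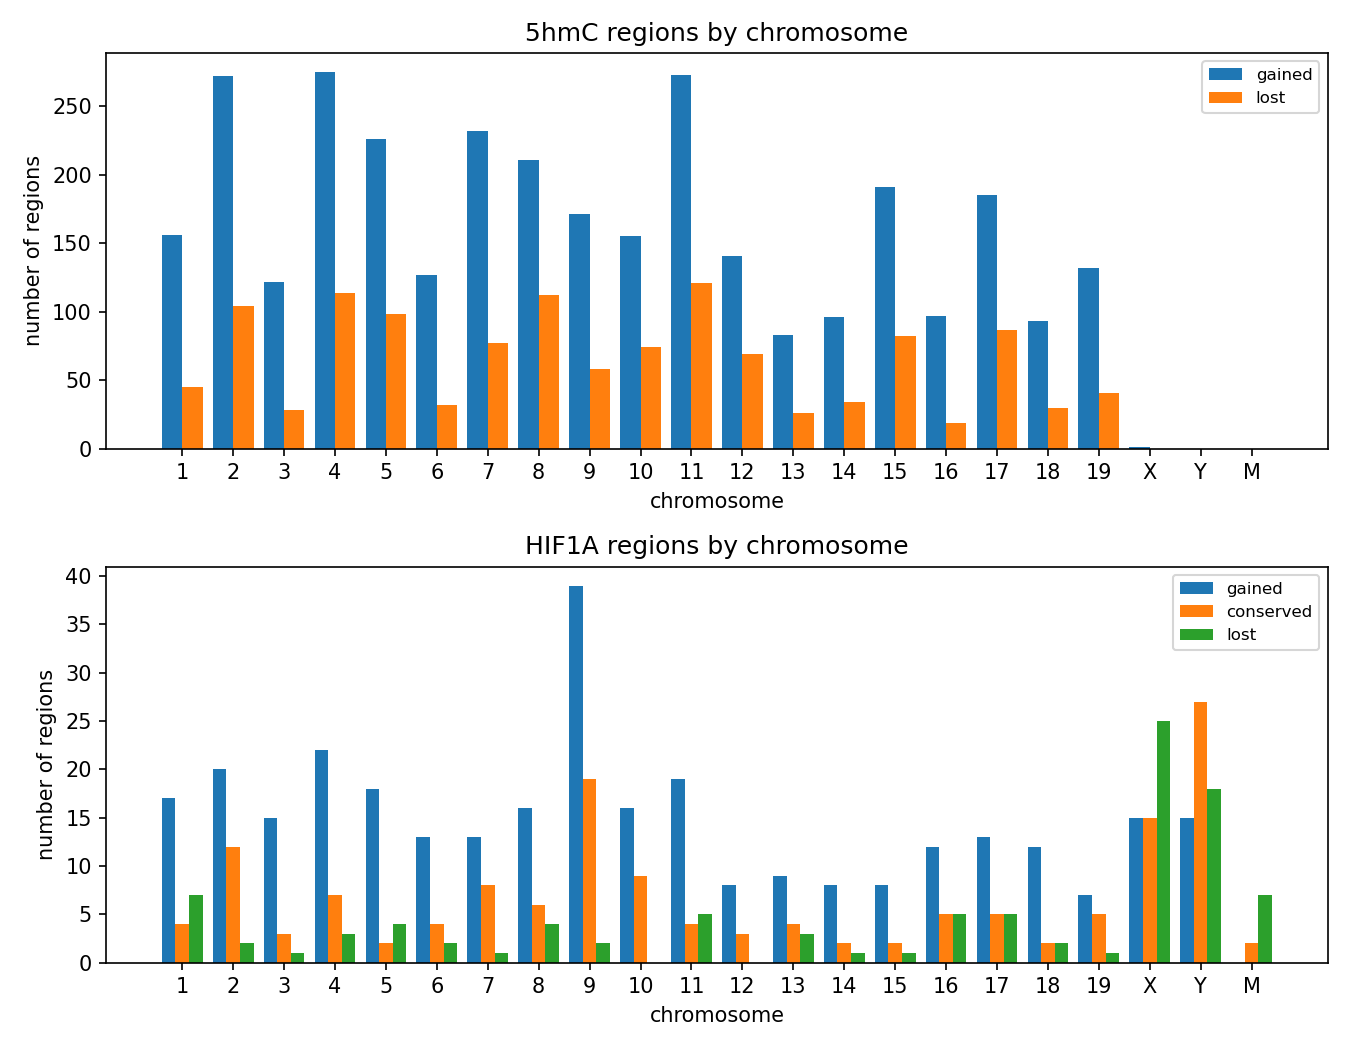
Number of regions per chromosome (M, mitochondrial) in the 5hmC lists, upper panel, and the HIF1A lists, lower panel, bars starting at 0. Gained 5hmC regions exceed lost ones on each autosome and X holds 1 region, while HIF1A regions are frequent on 9, X and Y.

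The HIF1A comparison asked how binding of this transcription factor changed with stress. The authors' lists held 315 gained, 150 conserved and 99 lost regions, so gains made up 76.1% of 414 changed regions (95% exact binomial interval 71.7 to 80.1%, two-sided exact binomial p = 2.52e-27). Gained and conserved regions come from 1 stressed set of 462 peaks, while peak numbers of lost regions reached 239, so this test also reflects a longer stressed peak list at unknown depth. Of lost regions 25.3% lay on chromosome X and 18.2% on Y, against 4.76% each of gained regions (two-sided Fisher exact p = 4.1e-08 and 7.22e-05), while conserved regions had 15 of 150 on X and 27 of 150 on Y. Regions of the lists were crowded on these chromosomes, with 28 in 43.2 kb of Y. They are therefore not independent, and the Fisher p-values describe the lists only. A further 7 lost regions lay on the mitochondrial genome, which held 0 of 315 gained regions. Without the sex chromosomes and the mitochondrial genome, a restriction chosen after the data were seen, 285 gained and 49 lost regions remained.

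The highest-scoring conserved HIF1A regions lay on chromosome 7 from 80763253 to 80763657 (score 3035.5), on chromosome 11 from 121097879 to 121098239 (score 2818) and on chromosome 4 from 154597234 to 154597632 (score 1905). The highest-scoring gained regions were on chromosome 2 from 173901500 to 173901883 (score 720.9), on chromosome 6 from 125115248 to 125115596 (score 485.8) and on chromosome 10 from 58785875 to 58786205 (score 468.8). The 3 highest-scoring lost regions were on the mitochondrial genome, from 1752 to 4801, from 1 to 1653 and from 11597 to 12596, with scores of 1203, 1035 and 469.6. That genome held 9 HIF1A regions within 15.7 kb, 7 lost and 2 conserved. Whether its signal reflects HIF1A binding was not tested. Median length was 96 bp for gained, 120.5 bp for conserved and 78 bp for lost regions, and gained exceeded lost regions by 18 bp (two-sided permutation test, p = 0.00187). HIF1A regions were crowded: 256 of 564 lay within 50 kb of another, including 36 in 38.2 kb of chromosome 9 from 3000001 to 3038230. Whether signal at such crowded places reflects binding was not tested either.

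Joining the assays asked whether stress-associated HIF1A binding and 5hmC change fell at the same places. Direct overlap was rare: 1 of 564 HIF1A regions overlapped a changed 5hmC region by at least 1 bp, against 0.339 on average in random placements (two-sided permutation of positions, p = 0.583). It was a conserved HIF1A region on chromosome 11 from 3000401 to 3000562, which contained a gained 5hmC region from 3000405 to 3000559, near the start of the assembled sequence of that chromosome. Gained HIF1A regions had 0 of 315 overlaps and conserved ones 1 of 150 (two-sided Fisher exact p = 0.323). Within 10 kb, however, 46 HIF1A regions lay near a changed 5hmC region, against a mean of 14.5 and a central 95% range of 8 to 22 in placements (two-sided permutation of positions, p = 0.0002, the smallest possible; 0.000956 after Benjamini-Hochberg adjustment over 43 placement comparisons).

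The proximity involved gained 5hmC. Of 315 gained HIF1A regions 30 lay within 10 kb of a gained 5hmC region, against 6.71 on average in placements, and 3 lay near a lost 5hmC region, against 2.95. Of 150 conserved HIF1A regions 9 lay near a gained 5hmC region, against 2.55 on average (two-sided permutation of positions, p = 0.002, adjusted p = 0.0086). Of 99 lost HIF1A regions 3 lay near gained 5hmC, against 1.18 on average (two-sided permutation of positions, p = 0.224, adjusted p = 0.642). The share near any changed 5hmC region was 10.5% for gained, 6.67% for conserved and 3.03% for lost HIF1A regions; gained against conserved gave p = 0.231 and gained against lost p = 0.0231, or 0.0693 after adjustment over 3 comparisons (two-sided Fisher exact tests). Placements kept each region on its chromosome but did not follow genes or sequence composition, which both kinds of region can share.

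**Figure D4:**
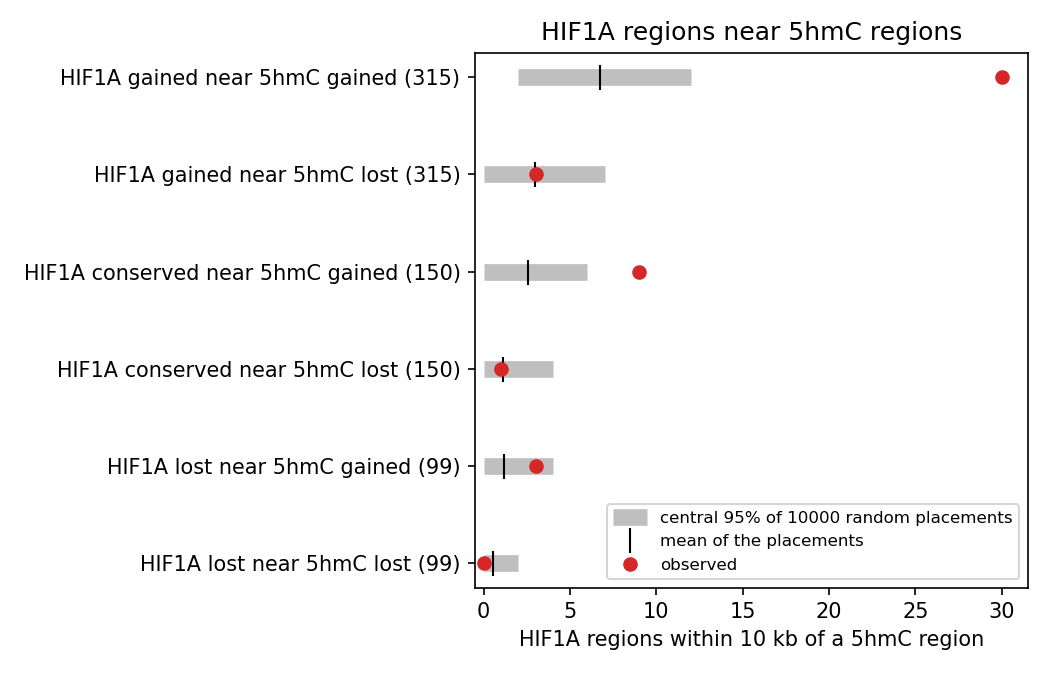
Number of HIF1A regions within 10 kb of a 5hmC region for each pair of lists (number of HIF1A regions in parentheses); points are observed numbers, grey bars the central 95% of 10000 random placements and ticks their mean. Gained and conserved HIF1A regions near gained 5hmC, 30 and 9, lie beyond their bars.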

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

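Tests with a score minimum of 100, with peak names counted once, on autosomes alone, without crowded HIF1A regions and without small RNA genes were chosen after the data were seen. The number of genes at least 2-fold lower, 1725, became 1078 after quantile normalization, and the number at least 2-fold higher, 22, became 45 and 51 with pseudocounts of 0.1 and 0.01, 187 after quantile normalization and 7 without microRNA, small nucleolar RNA and ribosomal RNA genes; a smaller pseudocount widens ratios of low genes, and the other causes were not tested. The single overlap of HIF1A and 5hmC regions exceeded the mean of placements, 0.339, whereas within 1 kb the same count of 1 was below a mean of 1.95, and both were within the range of placements. Within 10 kb the count passed the test: 46 regions, 43 on autosomes and 36 without HIF1A regions within 50 kb of another. The shares of gained regions stayed on their side of the test in each alternative run, from 69.95 to 77.3% for 5hmC and from 75.5 to 85.3% for HIF1A; taking the better-scoring part of each list fixes that share by construction. Calls with at least 1 or 5 FPKM numbered 232 and 209 of 233. Of 29 lists, 9 lay outside their random range as reported, 9 with a pseudocount of 0.1 or no filter and 7 after quantile normalization; in 87 list values under alternatives 81 kept their position, 4 moved inside the range (HIF components and blood markers after quantile normalization, neurotrophins there and with no filter) and 2 moved outside it (glycolysis after quantile normalization, oxidative phosphorylation with no filter). With no filter the oxidative phosphorylation median itself stayed the same, and only its random lists changed. For single named genes 42 of 78 alternative values differed by under 0.58 on the log2 scale. No paired analysis was possible because the RNA columns hold 1 value per group and the region lists none per sample. For the same reason leaving out replicates, other thresholds, models with a trend and correlation-adjusted list tests were not run; placements limited to gene spans were not run without annotation of the build. Depth limits are unknown, as the values carry no counts.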

Other observations

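Tests of a single scaling factor by quantile normalization, of lost HIF1A regions near others, of X and Y shares, of pituitary hormones, of gene symbol families and of 5hmC gains between autosomes were chosen after the results were seen; those leaving out abundant genes and of an abundance-dependent difference were set before theirs were seen.

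Gene families picked by symbol partly repeat the list results, because the ribosomal protein and complex I families share members with the fixed lists. Of 97 ribosomal protein symbols 90 were lower in the stressed group, with a median log2 difference of -1.60 against a random range of -0.97 to -0.34, and 3 were called in the authors' deposited table. Their median was -0.59 after quantile normalization. Of 37 complex I subunit symbols 35 were lower, with a median of -1.48 at the 1.02 percentile, below the random range, and 3 were called in the authors' deposited table. Quantile normalization brought that median to -0.67. The 77 mitochondrial ribosomal proteins had 68 lower members and a median of -0.83, the 46 proteasome subunits 44 lower and -0.91, and the 14 replication-dependent histone cluster genes 10 lower and -0.83; these 3 medians lay below their random ranges and stayed negative after quantile normalization. Of 29 small nucleolar RNAs 20 were lower and 9 higher, with a median of -1.72, and of 32 microRNA genes 18 were lower and 14 higher, with a median of -0.79 that turned to 0.23 after quantile normalization. Protocadherins, cell adhesion proteins of neurons, went the other way: 49 of 60 were higher, with a median of 0.16 against a random range of -0.09 to 0.11. For 310 zinc finger protein genes 189 were higher and 121 lower, with a median of 0.05 inside the random range, as were 60 potassium channel genes at 0.06 and 21 collagen genes at 0.06.

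The other cell type lists lay inside their random ranges. Microglia markers had 10 of 15 members lower and a median of -0.25, with C1qa, a complement subunit, at 217.9 and 28.1 FPKM but Csf1r at 27.7 and 30.3. Medians were -0.07 for 14 astrocyte, -0.17 for 19 myelin, -0.15 for 17 cortical layer and -0.07 for 13 interneuron markers, which turned positive after quantile normalization, and 0.09 for 9 oligodendrocyte precursor, 0.10 for 14 endothelial and 0.04 for 12 mural markers. The 21 heat shock and unfolded protein genes had 19 lower members and a median of -0.40, which became 0.11 after quantile normalization. Medians were -0.07 for 16 clock genes, -0.04 for 12 inflammatory genes and -0.22 for 7 striatal markers, with the same turn, and 0.04 for 17 monoamine receptors. Choroid plexus, olfactory and hippocampal, and sex-linked lists had under 5 measured members. Of the Y-linked genes, Ddx3y had 18.8 and 12.9 FPKM and Uty 3.43 and 3.32, while Eif2s3y had 20.6 and 23.1 and Kdm5d 4.09 and 5.19. The X-linked Xist had 0.0553 and 0.027 FPKM.

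5hmC regions were unevenly placed among chromosomes. Chromosome X held 1 of 4490 changed regions, from 166433824 to 166434087, where its 6.42% of the listed span would give 288.2. The lists hold changed regions only, so whether X had few 5hmC peaks, few changes or was left out of the lists cannot be told here. Gained regions were densest on chromosome 11, with 23.1 per 10 Mb, and among autosomes sparsest on chromosome 13, with 7.25. The gained share of regions ranged from 65.3% on chromosome 8 to 83.6% on chromosome 16, and the 19 autosomes differed when each peak was counted once (permutation test with 100000 resamples, p = 0.00046, or 0.000552 adjusted over 6 tests).

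The calls of the authors' deposited table went 1 way, with 233 lower and 0 higher in the stressed group. Quantile normalization works on ranks and so takes out any single scaling factor and any abundance-dependent difference between the value distributions. It moved the median of the called genes from -2.30 to -1.99, with 232 of 232 lower. These genes were called from the same values, so most of their fall was likely to remain. The test therefore does not decide against either source. The median of the 12971 genes was -0.04, so no single factor lowered all genes alike. The 100 most abundant genes took 32.9% of the control sum and 15.2% of the stressed sum. Without them, after rescaling, the median of the called genes with a stressed value above 0 was -1.95. Its starting value was -2.61, the median of the authors' log2 changes, and not the log2(FPKM + 1) median of -2.30. This test has the same limit. Transcript length, base composition and the integrity of the RNA stay open. Rpph1 and Rmrp, the steepest called falls among genes above 0 in both groups, are short RNAs. Mir6392 and Snora41, among the largest higher values, are short too, but both rest on a 0 in control. Of their families, 20 of 29 small nucleolar RNAs and 18 of 32 microRNA genes were lower. In the list fixed as a sign of RNA quality, at the 99.7 percentile, Malat1 at 178.05 and 108.7 FPKM and Mirg at 14.1 and 9.45 were lower, while Rn45s rests on a 0 in control. An effect of stress itself also stays open and was not tested apart from these.

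HIF1A regions were crowded at a few places: 3 places of at least 10 regions, on chromosome 9 from 3000001 to 3038230 and on Y from 2855727 to 2898903 and from 2781942 to 2791255, held 74 of 564 regions. Of 99 lost regions 39 lay within 10 kb of a gained or conserved one, against a random range of 7 to 13. None overlapped, which such lists can show by construction. Small differences in where peaks passed the threshold at shared places of high signal may therefore account for some gains and losses. Animals of different sex in the control and stressed libraries would move X and Y shares in opposite directions, but both were higher among lost regions, with 7.22e-05 as the larger two-sided Fisher exact p. That p treats crowded regions as independent, so it describes the lists and cannot decide on the sex of the animals. The 209 gained and 43 lost regions without a neighbour within 50 kb keep the excess of gains. A longer stressed peak list at unknown depth would also keep it, so this count does not separate the explanations. Stress remains an untested explanation for these regions.

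Growth hormone and prolactin RNA had higher values in the stressed group: Gh had 0.0184 and 27.2 FPKM and Prl 0.0187 and 9.56 FPKM, without calls in the authors' deposited table. RNA of pituitary tissue in a stressed library could bring these, and 5 of 7 pituitary hormone genes had a higher stressed value, with Cga at 0.696 FPKM and listed at 0 in control. Pomc, which the control group also expressed, had 5.62 and 2.67 FPKM, and Tshb 0.156 and 0.119. With 1 value per group, such tissue in 1 sample and an induction of both genes in cortex by stress cannot be told apart.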
